A study of Mus musculus with 16 samples.

How the data were processed

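Gene expression was measured on Clariom S mouse arrays (Affymetrix) in sorted cells of the olfactory mucosa from S100a5-tauGFP mice. The series holds 16 arrays from 8 pools of 3 mice. For 4 pools the exposure was 2-octanone and for 4 it was vehicle, and each pool was sorted into a GFP+ and a GFP− fraction. Per the labels, 50 to 100 ng of total RNA per fraction was turned into biotinylated cRNA, and the submitters' processing notes name Affymetrix Expression Console as the software that made the values. The deposited table holds 28846 probe sets in 16 columns with values from 2.13 to 18.99. These were read as the authors' normalised signals on the log2 scale, since their range is that of log2 array signals. The sources used here state neither the log base nor the normalisation algorithm. The precision is limited by the number of arrays, 4 per group.

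Of the 28846 probe sets, 6640 were controls and 2634 named no gene. The other 19572 each named 1 gene through an Entrez identifier, and all 19572 identifiers were found in a table of mouse RefSeq genes. They stood for 19505 symbols, of which 55 had more than 1 probe set. A gene with several probe sets was tested per probe set and is described by the one with the highest mean over all arrays. No genome build is named with the arrays, so no coordinates are given.

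All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the means of the 4 groups. The fit left 12 residual degrees of freedom, and the prior held 4.19. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were GFP+ against GFP− cells over both exposures and within each, 2-octanone against vehicle within each fraction, and the change of the GFP+/GFP− ratio with 2-octanone. Odorant receptors, taken by symbol with pseudogenes left out, were also counted with p adjusted over the list alone. A receptor was to count as a candidate for 2-octanone where its ratio rose past that threshold and its difference in GFP+ cells was positive.

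The 30 gene lists covered receptor families, signalling pathways and markers of the cell types that the sort could hold. Besides the receptor families they held 333 genes, of which 35 were not named on the array, and 29 lists were tested. The sex-linked list served as a check of the pools. Lists were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. The comparisons, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined.

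The rule for named genes took S100a5 and Omp in every case. For the sort it took the 8 genes with the largest difference in each direction among those called with the same sign in both exposures. For 2-octanone in GFP+ cells and for the ratio it took the 12 receptors higher and the 4 lower with the smallest p, and 6 other genes in each direction, called or not. For GFP− cells it took 3 genes in each direction, and for each list with a call the 2 to 4 members with the smallest p. Only some of the genes that the rule gave are named in the text, and the arrays and pools whose values are given singly were chosen after their values were seen.

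Both fractions of a pool came from the same mice, so the pool pairs the arrays in the sort and in the ratio. The replicate number was checked as a pairing of the exposures through correlations of the residuals from the group means across genes. These were 0.19, 0.17, 0.26 and 0.43 for replicates 1 to 4 in GFP+ cells, and 0.34, −0.06, 0.35 and 0.52 in GFP− cells. Residuals are taken from the mean of 4 arrays, so a deviation shared by the replicate 4 arrays shifts the other residuals of both exposures alike. Correlations of unlike numbers were not compared, so these values cannot show that the numbers pair the exposures. The main fit used the group means only and paired no arrays. The replicate number entered only as a block in an alternative setting, given for both fractions. In GFP+ cells every correlation was over 0.1, and in GFP− cells that of replicate 2 was not, although both fractions came from the same pools.

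The alternative settings fixed with them were quantile normalisation, centring each array on its median, leaving out probe sets under the median mean signal, including unnamed probe sets, limma's trend and robust options, a threshold of 0.1, fitting only the arrays compared, leaving out each pool in turn, and the pool or the replicate number as a block, fixed or random. Alternatives chosen after seeing the data were leaving out both replicate 4 pools, array weights, the mean of the neutrophil genes as a covariate in GFP+ cells, leaving out each pool in the list tests, and the mean of both fractions of each pool. Every comparison was also run on other splits of the arrays. The unblocked limma fit of each comparison was tested on simulated data with known changes of 1 and of 2, each added to 100 genes. Camera at the preset correlation was tested there on a list of 10 genes without correlation between them. The blocked fits, the other list tests, the array weights and the splits were not tested on simulated data. At a change of 1 on the log2 scale the fit recovered 73 of the 100 in the comparison of exposures in GFP+ cells, 77 in GFP− cells and 34 for the ratio. At a change of 2 it recovered 97, 96 and 91. Of 10 changed receptors, adjusted over the list alone, it recovered 1 in GFP+ cells, 6 in GFP− cells and 0 for the ratio at a change of 1, and 9, 10 and 4 at a change of 2, with 3, 7 and 1 unchanged receptors called. Each comparison was simulated once, with values drawn independently for every gene and array, so effects shared within pools or between genes were not modelled. The GFP+ and GFP− comparisons have the same design and median receptor SE (0.351), so 1 against 6 recovered shows no difference in power. Control probe sets were left out of all tests, and unnamed probe sets were tested only as an alternative. Raw scans were not used here.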

Results

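The arrays measured RNA in cells sorted from the olfactory mucosa of S100a5-tauGFP mice, a strain in which GFP reports the activity of olfactory sensory neurons (OSNs). The 24 mice, 7 to 12 weeks old and of both sexes, spent 40 h in chambers fed with clean air at 3.1 L/min. From 26 h on, 4 pools of 3 mice received pulses of 2-octanone, a ketone odorant, lasting 10 s and coming every 20 min, and 4 pools received filtered air as vehicle. Each pool gave 1 array of GFP+ and 1 of GFP− cells, so that each of the 4 groups held 4 arrays. Array medians lay between 7.64 and 8.01 (log2 signal), and background probe sets averaged 5.40 to 5.61. The correlation across probe sets between arrays of one group was 0.982 to 0.995. The first principal component, which parted the GFP+ from the GFP− arrays, held 69.2% of the variance.

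S100a5, the gene after which the reporter strain is named, and Fos, an immediate early gene, stood apart in the replicate 4 pools of both exposures. In GFP+ cells S100a5 read 16.98, 16.63, 16.80 and 13.92 in the 4 pools given 2-octanone and 16.71, 16.47, 16.47 and 13.22 in the 4 given vehicle. In GFP− cells Fos read 12.30, 14.06, 13.19 and 16.01 after 2-octanone and 13.31, 13.76, 13.66 and 15.56 after vehicle. The Y-linked gene Eif2s3y read 3.48 to 5.31 on the arrays of the replicate 1 pools and 11.05 to 12.63 on all others, in both exposures alike.

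**Figure D1:**
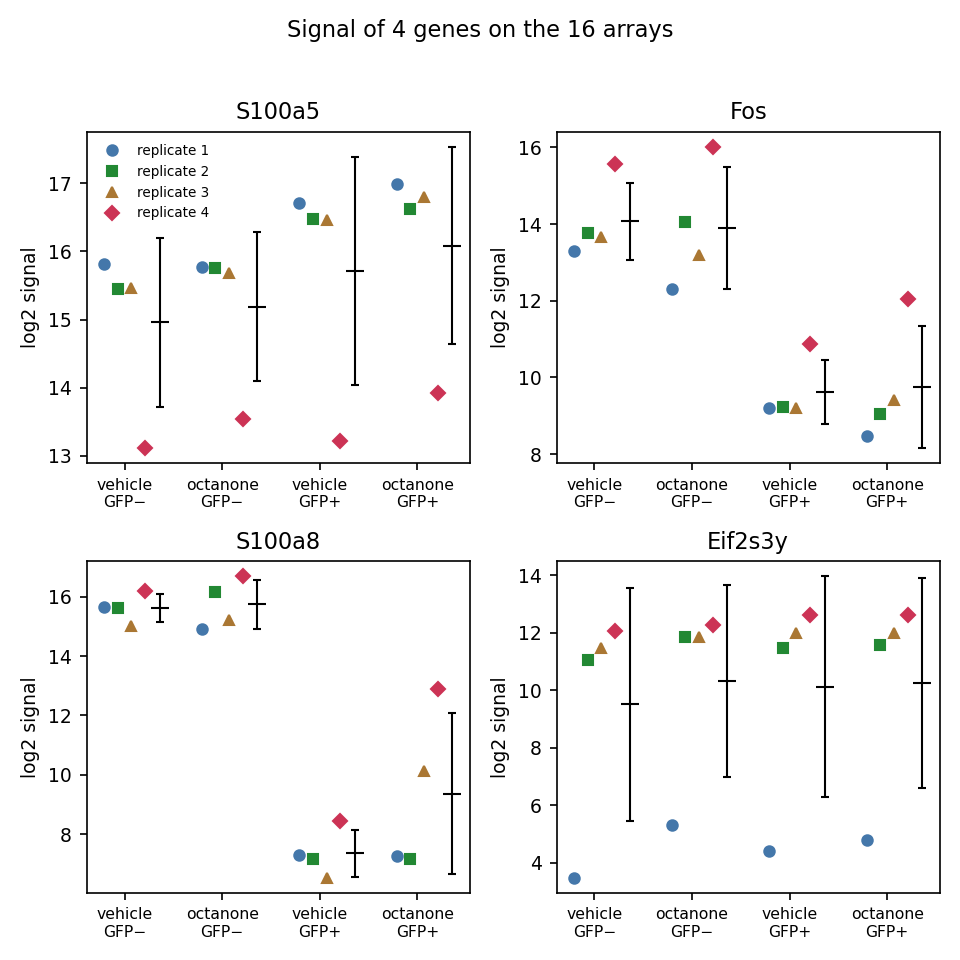
Signal (log2) of S100a5, Fos, S100a8 and Eif2s3y on each of the 16 arrays, by group (x axis), with symbols for the replicate number and a bar for the mean ± SD of 4 arrays. S100a5 is lowest and Fos highest in the replicate 4 pool of every group.

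The comparison of GFP+ with GFP− cells asks which genes separate reporter-positive cells from the rest. GFP+ cells held less RNA of neutrophil, dividing, microvillar, lymphocyte and precursor cell genes, more RNA of several genes of mature neurons and odorant signalling, and odorant receptors in both directions. With an estimated correlation the microvillar, lymphocyte and precursor lists remained called, and the neutrophil and dividing cell lists (adjusted p = 0.0978 each), the odorant signalling list (0.587) and the mature neuron list (0.633) did not. The largest differences downwards were mostly in genes of neutrophils and other myeloid cells: Ly6c2 differed by −7.57 (SE 0.61, log2, n = 4 pools per exposure), the resistin-like gene Retnlg by −7.43, the collagenase gene Mmp8 by −7.37, the calprotectin subunit gene S100a8 by −7.31 and the iron-binding lipocalin gene Lcn2 by −7.15. The largest upwards were odorant receptors: Olfr309 at 4.65 (SE 0.30), Olfr481 at 4.53, Olfr536 at 4.48, Olfr110 at 4.38 and Olfr613 at 4.32. In all, limma called 6000 of 19572 genes, 3263 higher and 2737 lower in GFP+ cells. Within exposures it called 3633 after vehicle (1475 higher, 2158 lower) and 2955 after 2-octanone (1036 higher, 1919 lower), and the 2395 called in both had the same sign in both. The median difference of all genes was 0.13. With each array centred on its median it was 0.41, and 15141 genes were called, 86.4% of them higher against 54.4% before. The array medians averaged 7.70 after 2-octanone and 7.68 after vehicle in GFP+ cells, and 7.96 and 7.98 in GFP− cells. Centring therefore raised every difference in the sort by the same amount. With the pool as a block, which pairs the fractions, limma called 7038 over both exposures, 4288 after vehicle and 3855 after 2-octanone. Without octanone replicate 2 and with no block the count after 2-octanone was 1963.

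Among 1080 odorant receptors, 484 were higher and 280 lower in GFP+ cells over all genes tested, and 504 and 297 adjusted over the list alone. Their differences ran from −6.18 to 4.65, with 149 over 4-fold higher and 146 over 4-fold lower. Olfr827 differed by −4.57 (SE 0.15, n = 4 pools per exposure), Olfr393 by −5.12, Olfr411 by −4.93 and Olfr1447 by −4.63. The receptors as a list were not called (median 0.39, adjusted p = 0.318, camera), and after median centring the list test turned to lower (adjusted p = 0.0273). The differences after vehicle and after 2-octanone were alike across receptors (r = 0.977, rho = 0.970; receptors are not independent replicates). They had the same sign for 1004 of 1080, and all 523 receptors called in both exposures kept it. Of 14 trace amine-associated receptors, which detect volatile amines, 7 were higher and 6 lower, among them Taar4 at 2.32, Taar2 at −3.34 and Taar7a at −2.55. That list was not called (adjusted p = 0.614); its median was 0.71, its mean −0.09 and the direction of the test downwards.

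**Figure D2:**
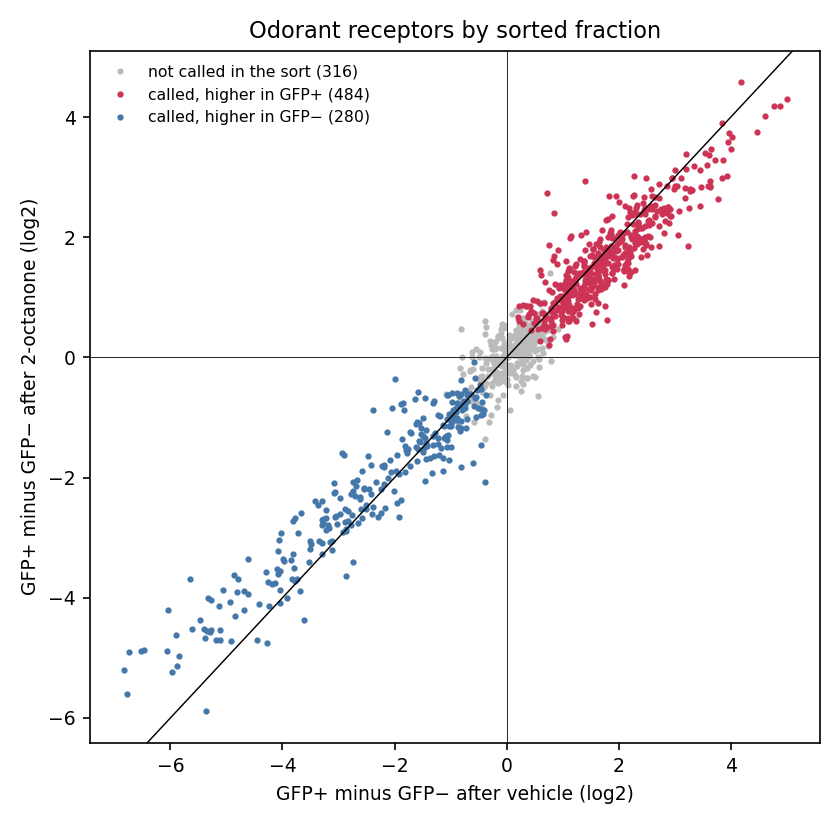
GFP+ minus GFP− difference (log2) of 1080 odorant receptors after vehicle (x axis) and after 2-octanone (y axis), with the line of equal values. Each point is a receptor, coloured by its call over both exposures (484 higher, 280 lower, 316 not called). After median centring of the arrays the receptors as a list test lower rather than higher.

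S100a5 differed by 0.83 between GFP+ and GFP− cells over both exposures (SE 0.60), which was not called (adjusted p = 0.304). It was higher in GFP+ cells in each of the 8 pools, and with the pool as a block, which pairs the fractions of the same mice, it was called (adjusted p = 0.000487). Without both replicate 4 pools, an alternative chosen after seeing the data, it was also called (1.02, adjusted p = 5.66e-06). It was called in those 2 of 18 alternatives, over which the difference ran from 0.77 to 1.11 and the adjusted p up to 0.407. Omp, a marker of mature OSNs, differed by 0.15 (limma adjusted p = 0.206). Only median centring called it among its 18 alternatives (0.43, adjusted p = 0.000633, and up to 0.481 in the others). Its signal was 17.76 to 18.45 on all arrays, near the largest value of 18.99, and whether a ceiling limits its difference was not tested. The 10 measured genes of the activity-dependent list held 6 higher and 1 lower. Pcp4l1 (1.69), Pcdh10 (1.51) and the axon guidance gene Sema7a (0.88) were higher and the calcium-binding protein gene Calb2 (−2.98, SE 0.11) was lower. The list itself was not called (median 1.02, adjusted p = 0.235; 0.740 with an estimated correlation), though at the preset correlation it was with the pool as a block (adjusted p = 0.0144) and without both replicate 4 pools (0.0377).

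Markers of several cell types other than mature neurons were lower in GFP+ cells, and the preset correlation called 14 of the 29 lists. Fry called 19 lists, these 14 among them (adjusted p = 1.37e-06 for neutrophil and 1.30e-06 for proliferation genes). With an estimated correlation 3 of the 14 remained called. These were the globose basal and precursor list (8 of 10 genes lower, among them Kit at −3.20, SE 0.11, and Neurog1 at −1.01, below background in GFP+ cells; median −1.19; adjusted p = 5.61e-08, and 0.0301 with an estimated correlation), the microvillar list (all 11 lower, with the taste-type channel gene Trpm5 at −3.25 and Pou2f3 at −2.14; median −2.66; 3.18e-14 and 0.0422) and the lymphocyte list (all 7 lower, with the B cell receptor genes Cd79a at −3.01 and Cd79b, at background in GFP+ cells after vehicle; median −1.99; 1.21e-07 and 0.0422). All 10 neutrophil genes were lower (median −7.04, adjusted p = 1.58e-13; 0.0978 with an estimated correlation). All 14 proliferation genes were lower, with the cell-cycle genes Mki67 at −5.21 (SE 0.38) and Bub1 at −3.54, the latter at background in GFP+ cells, so that its difference is a lower bound in size (median −2.31, adjusted p = 7.03e-15; 0.0978 with an estimated correlation). Of 15 genes of immature OSNs 9 were lower, including the G protein subunit gene Gng8 at −4.05, Nhlh1 at −4.01 and Dpysl3 at −3.27 (median −0.77, adjusted p = 1.92e-08; 0.0978 with an estimated correlation). Of 13 macrophage genes 9 were lower, including Tyrobp at −4.09 and the antigen-presentation gene H2-Ab1 at −4.52 (median −1.66, adjusted p = 8.22e-09; 0.151 with an estimated correlation).

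Of 18 immediate early genes, whose transcription follows stimulation within minutes, 12 were lower in GFP+ cells and 1 was higher. Fos differed by −4.30 (SE 0.56), Egr1 by −2.88 and Nr4a2 by −0.97 (list median −0.93, adjusted p = 1.68e-06; 0.151 with an estimated correlation). The smaller groups called lower were the 2 erythroid genes (Slc4a1 at −2.28; adjusted p = 0.00543; 0.139 with an estimated correlation), the list for neurons with guanylyl cyclase D (3 of 7 lower, Pde2a at −3.22; 0.00792; 0.176 with an estimated correlation) and the sustentacular list of supporting cells. Of the last, 5 of 13 genes were lower, with the keratin gene Krt18 at −2.35 (median −0.20, adjusted p = 0.00792; 0.580 with an estimated correlation). After median centring its median was 0.08 while the list test still called it lower (adjusted p = 0.00103).

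Genes of mature neurons lay on the other side. Of 18 olfactory transduction genes 10 were higher and 1 lower, with the chloride channel gene Ano2 at 0.53 and the phosphodiesterase gene Pde1c at 0.72 (list median 0.33, adjusted p = 0.0126; 0.587 with an estimated correlation). Of 16 genes of mature OSNs 7 were higher, such as the glutamate transporter gene Slc17a6 at 0.42 (median 0.26, adjusted p = 0.0200; 0.633 with an estimated correlation). Of 11 genes of ciliated respiratory cells 5 were higher, such as the cilium gene Tekt1 at 0.54 (median 0.45, adjusted p = 0.0353; 0.293 with an estimated correlation). After median centring Ano2, Slc17a6 and Tekt1 stood at 0.81, 0.69 and 0.82. The ciliated list was not called after median centring (adjusted p = 0.102), without vehicle replicate 1 (0.0568) or without both replicate 4 pools (0.0681).

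The other lists were not called by the preset correlation in the sort. Axon guidance genes had 9 of 18 higher and 2 lower (median 0.26, adjusted p = 0.177), calcium signalling genes 3 of 15 higher and 4 lower (0.12, 0.417), heat shock genes 1 of 9 higher and 4 lower (−0.24, 0.0552) and Bowman's gland genes 2 of 9 lower (−0.17, 0.0552). With the pool as a block the heat shock (adjusted p = 0.0119) and Bowman's gland (0.0246) lists were called lower, while neither was with an estimated correlation and no block (0.151 and 0.587). So was Bowman's gland after median centring (0.00733) and without octanone (0.0439) or vehicle replicate 1 (0.0461). Heat shock was called lower after quantile normalisation (0.0488), with array weights (0.0467) and without octanone replicate 3 (0.0495) or 4 (0.0409), vehicle replicate 4 (0.0496) or both replicate 4 pools (0.0258). Fry called both lists lower. The remaining medians were 0.04 for horizontal basal cells (adjusted p = 0.846), 0.15 for ensheathing glia (0.956), −0.09 for endothelium (0.235), 0.09 for fibroblasts (0.883), −0.12 for the dorsal zone (0.299), 0.11 for the ventral zone (0.828), 0.03 for the unfolded protein response (0.857) and −0.01 for xenobiotic metabolism (0.828). After median centring the medians of heat shock (0.04), Bowman's gland (0.11), endothelial (0.19), dorsal zone (0.16) and xenobiotic metabolism genes (0.27) were positive, though the heat shock and Bowman's gland tests kept their downward direction, and after quantile normalisation that of horizontal basal genes was −0.04. The direction of the test was downwards, against the sign of the median, for calcium signalling, horizontal basal and unfolded protein response genes.

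**Figure D3:**
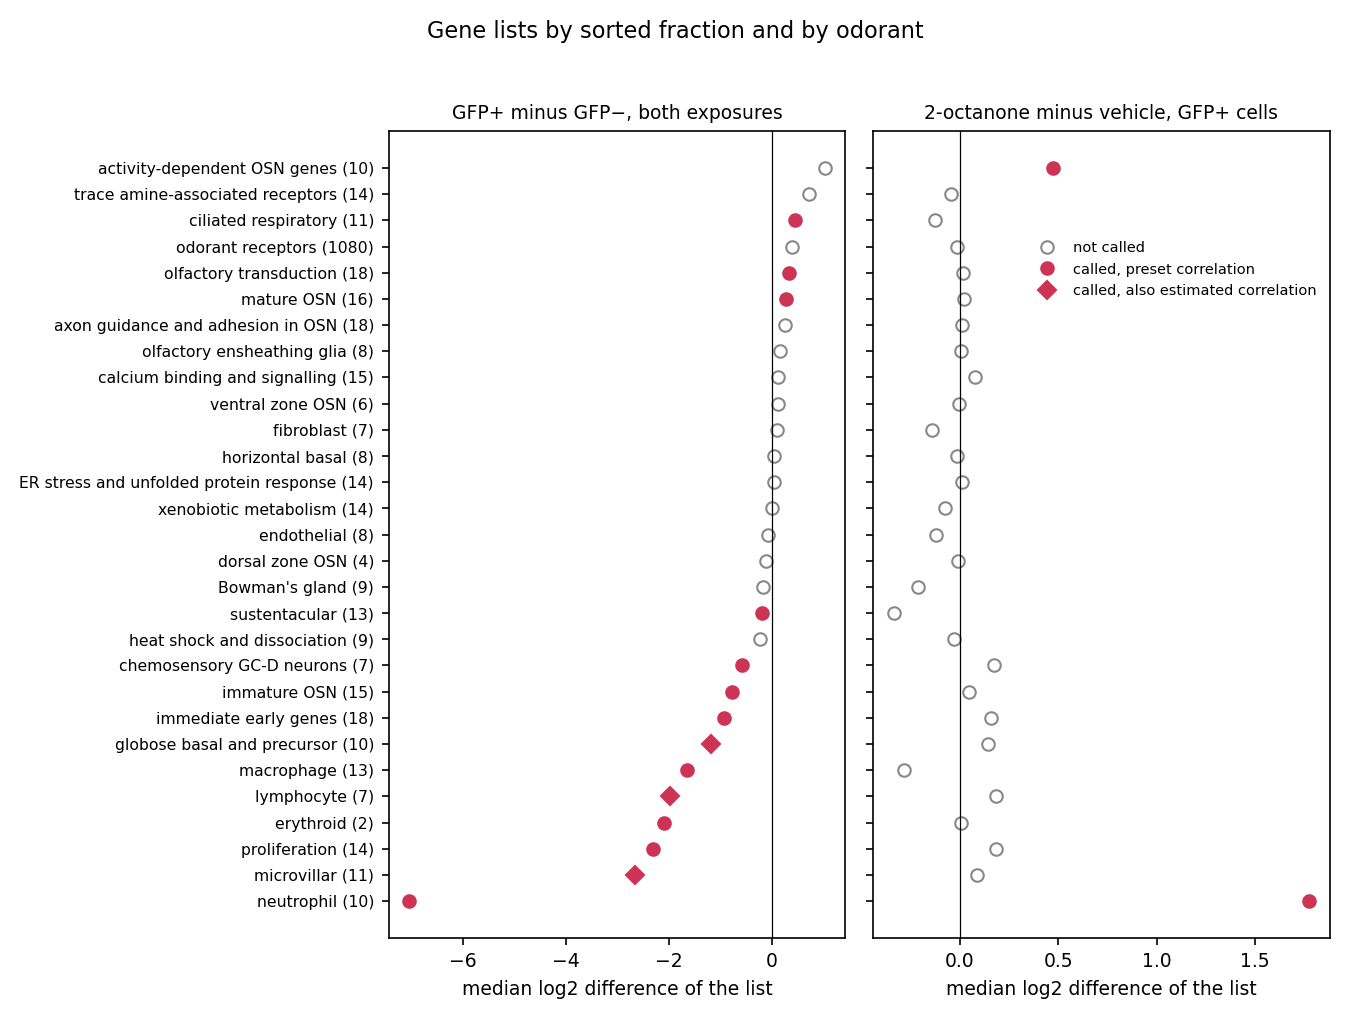
Median log2 difference of 29 gene lists (measured members in brackets) between GFP+ and GFP− cells and between 2-octanone and vehicle in GFP+ cells. Filled points were called by camera at the preset correlation and diamonds also with an estimated one. After median centring the sort medians of the sustentacular, Bowman's gland, heat shock, endothelial, dorsal zone and xenobiotic lists are above 0 and the receptor list tests lower, and after quantile normalisation the horizontal basal median is below 0.

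The comparison of 2-octanone with vehicle in GFP+ cells asks which genes, receptors above all, the odorant brought into the reporter-positive fraction. No gene was called by limma: 0 of 19572, with 618 at an unadjusted p under 0.05 (345 higher, 273 lower) and a smallest adjusted p of 1.000. No receptor was called adjusted over the list alone either (0 of 1080, with 57 at an unadjusted p under 0.05), where a single simulated data set recovered changes of 1 and 2 in 1 and 9 of 10 receptors. With the replicate number as a block, which takes arrays with the same number as pairs, 0 genes and 1 receptor were called, Olfr1098 at −1.51 (SE 0.136, adjusted p = 0.0142 over the list alone; 0.246 unblocked). The receptor with the smallest p was Olfr117, at 11.87 ± 0.30 after 2-octanone and 10.58 ± 0.67 after vehicle (mean ± SD, n = 4), a difference of 1.29 (SE 0.26, limma adjusted p over the list alone 0.179). It was called without vehicle replicate 4 (1.53, adjusted p over the list alone 0.0139) and with array weights (1.37, 0.0477), and Olfr1213 was called without vehicle replicate 2 (2.29, 0.0210). Other receptors with small unadjusted p, none called with all pools, differed by 1.72 for Olfr77 (SE 0.42), 1.18 for Olfr393 (SE 0.31), 1.77 for Olfr1213 (SE 0.47), 0.90 for Olfr459, 1.43 for Olfr1384, 1.58 for Olfr390 and −2.48 for Olfr1202 (SE 0.63). Without octanone replicate 4 the difference was 0.89 for Olfr390 and 0.94 for Olfr1384, and without both replicate 4 pools 0.87, 0.88, 0.58 for Olfr459 and −1.36 for Olfr1202. With the neutrophil mean as a covariate, added after seeing the data, it was 0.71 for Olfr390, 0.74 for Olfr1384, 0.76 for Olfr393 and 0.54 for Olfr459. After vehicle, 6 of these (Olfr77 at −5.65, Olfr393 at −6.04, Olfr1213 at −6.52, Olfr459 at −4.86, Olfr1384 at −6.46 and Olfr390 at −6.74) were lower in GFP+ than in GFP− cells.

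**Figure D4:**
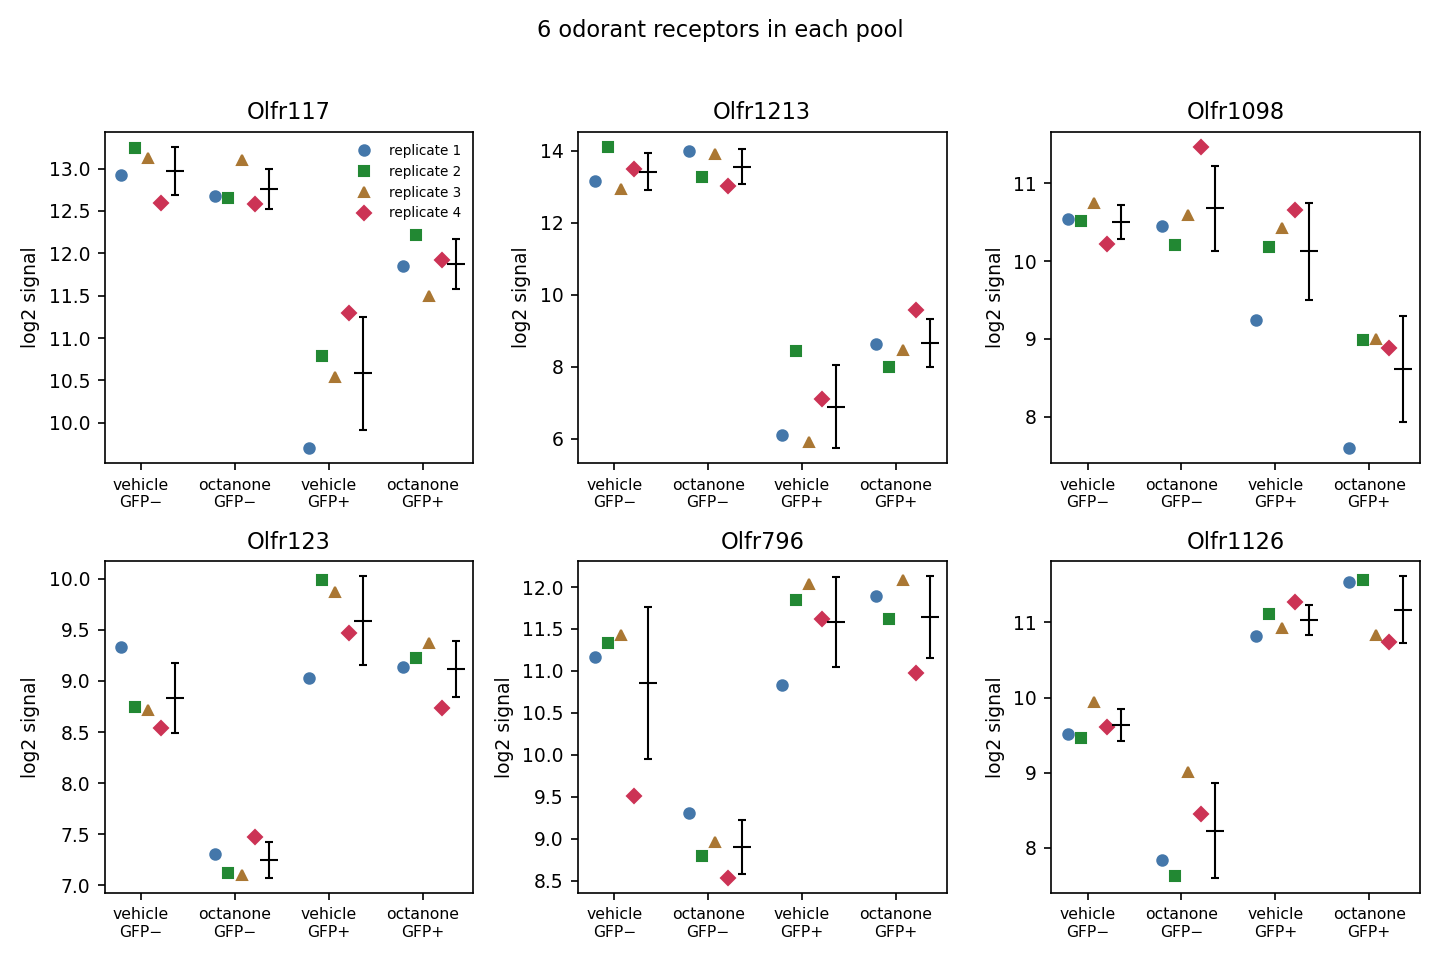
Signal (log2) of 6 odorant receptors in each pool, by group (x axis), with symbols for the replicate number and a bar for the mean ± SD of 4 arrays. In GFP− cells Olfr123 read 7.25 ± 0.18 after 2-octanone and 8.83 ± 0.34 after vehicle.

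Outside the receptors, the cell adhesion gene Pcdh10, whose expression in OSNs depends on activity, read 12.84, 12.18, 11.07 and 10.49 in GFP+ cells after 2-octanone and 9.55, 10.43, 9.53 and 8.72 after vehicle. Its difference of 2.09 (SE 0.51) was not called over all genes (limma adjusted p = 1.000), and in GFP− cells it was 1.99. The calmodulin kinase inhibitor gene Camk2n1 differed by 1.01 (SE 0.20), the potassium channel gene Kcnn3 by 0.90 (SE 0.22) and the cystathionine gamma-lyase gene Cth by −0.65, none of them called. The vomeronasal receptor genes Vmn2r40 (−0.69, SE 0.13) and Vmn2r33 (−0.73), not called either, read near or below background in all groups. In the unpaired fit S100a5 differed by 0.37 (SE 0.85), but by −0.47 without vehicle replicate 4, and Omp by 0.03 (SE 0.13). Within each replicate number S100a5 read higher after 2-octanone (16.98 against 16.71, 16.63 against 16.47, 16.80 against 16.47 and 13.92 against 13.22). The replicate 1 pools of both exposures shared low Eif2s3y, and the replicate 4 pools of both shared low S100a5 and high Fos. These numbers thus joined like pools. Without vehicle replicate 4, the low value of octanone replicate 4 (13.92) has no like pool on the other side. Whether the numbers pair all the pools was not settled.

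Camera called 2 lists in GFP+ cells, both higher after 2-octanone. The activity-dependent OSN list had a median of 0.47, with 9 of 10 genes positive and 1, Pcdh10, called adjusted over the list alone (adjusted p = 3.64e-05; 0.756 with an estimated correlation). The neutrophil list had a median of 1.77, with all 10 genes positive and none called, Lcn2 at 2.50 (SE 1.04) and S100a8 at 2.00 (SE 0.91) among them (adjusted p = 2.50e-08; 0.756 with an estimated correlation). Without octanone replicate 4 Lcn2 differed by 1.24 and S100a8 by 0.83. The mean signal of the neutrophil genes in the GFP+ arrays was 7.15, 7.14, 9.67 and 12.45 after 2-octanone and 7.15, 7.31, 6.71 and 8.19 after vehicle, so that it stood apart in octanone replicates 3 and 4. In these GFP+ fractions the neutrophil genes exceeded their mean in vehicle GFP+ cells by a median of 2.53 and 6.74% of the same pool's GFP− signal, and 53 receptors at least 4 (log2) higher in GFP− cells after vehicle exceeded theirs by 2.44 and 6.24%. Fry called 0 lists. With the replicate number as a block 5 lists were called, the others being immediate early genes higher (adjusted p = 0.000499), and sustentacular (0.00173) and Bowman's gland genes (0.0332) lower; with an estimated correlation and no block none of these 3 was called (adjusted p = 0.977 each). The number of lists called was 4 without octanone replicate 1, 2 or 4 or vehicle replicate 2, and 7 without vehicle replicate 3.

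**Figure D5:**
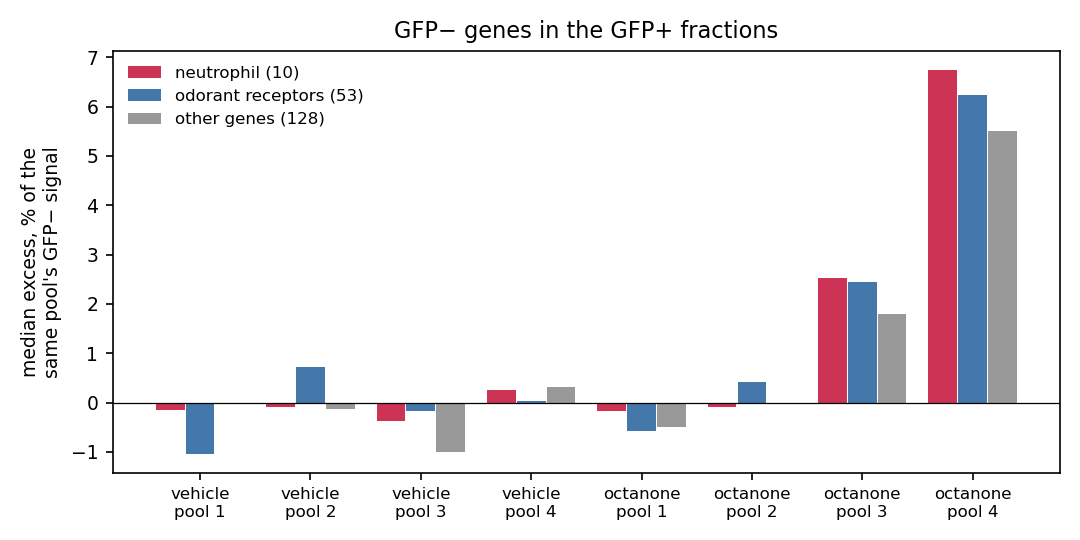
Median excess of signal over the other vehicle GFP+ arrays, as % of the same pool's GFP− signal, in the GFP+ fraction of each of the 8 pools (x axis), for genes at least 4 (log2) higher in GFP− cells after vehicle. Bars stand for 10 neutrophil genes, 53 odorant receptors and 128 other genes, and reach 6.74, 6.24 and 5.51% in octanone pool 4.

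The same comparison in GFP− cells gives the background for the effect in GFP+ cells. Limma called 1 gene, the odorant receptor Olfr123, which fell by 1.58 (log2) after 2-octanone (SE 0.215, adjusted p = 0.0289), from 8.83 ± 0.34 to 7.25 ± 0.18 (mean ± SD, n = 4), and 477 genes had an unadjusted p under 0.05 (243 higher, 234 lower). Adjusted over the list alone, 3 of 1080 receptors were called, all lower: Olfr123 (adjusted p = 0.00159), Olfr796 (−1.96, SE 0.38, 0.0304) and Olfr1126 (−1.40, SE 0.27, 0.0304). In a single simulated data set for this comparison 7 unchanged receptors were called beside 6 and 10 of 10 changed ones at a change of 1 and 2. Olfr398 differed by −2.14 (SE 0.55) and was not called, but it was over the list alone without vehicle replicate 4 (−2.74, 0.00773), without both replicate 4 pools (−2.54, 0.00643) and with array weights (−2.39, 0.0159). The chemokine gene Cxcl9 differed by −1.06 (SE 0.19, adjusted p = 0.340), not called and at background after 2-octanone. Over all genes Olfr123 was not called when only these arrays were fitted (adjusted p = 0.136), nor without octanone replicate 1 (0.277), 2 (0.402), 3 (0.148) or 4 (0.0558) or vehicle replicate 2 (0.113) or 3 (0.150), without both replicate 4 pools (0.0662) or with the pool as a random block (0.0701). With the replicate number as a block Olfr123 was not called either (limma adjusted p = 0.171). Over 19 alternatives the difference of Olfr123 ran from −1.76 to −1.42. Its adjusted p over all genes ran from 0.00424 to 0.402, with 9 calls. Adjusted over the list alone, Olfr123 was called in every alternative (limma adjusted p at most 0.0222, without octanone replicate 2). Olfr796 and Olfr1126 were not called over the list when only these arrays were fitted. Without vehicle replicate 4, Olfr796 was called as well over all genes (−2.41, adjusted p = 0.0169), and the number of receptors called over the list alone was 1 without any one of octanone replicates 1, 2 and 4 or vehicle replicates 1, 2 and 3.

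In the lists, camera called 3 in GFP− cells. Genes of immature OSNs were lower after 2-octanone, with 14 of 15 negative (median −0.27, adjusted p = 0.000160; 0.904 with an estimated correlation), as were globose basal genes (median −0.18, adjusted p = 0.0111; 0.817 with an estimated correlation), with Kit at −0.50. Activity-dependent OSN genes were higher (median 0.24, adjusted p = 0.0111; 0.965 with an estimated correlation). The immature OSN call was lost without octanone replicate 4 (adjusted p = 0.230), the globose basal call without octanone replicate 1 (0.0517) or vehicle replicate 4 (0.481), and the activity-dependent call without octanone replicate 1 (0.104) or 3 (0.157) or vehicle replicate 4 (0.256). Without both replicate 4 pools the immature OSN (0.785) and globose basal (0.883) lists were not called. Lists called numbered 6 without octanone replicate 4 and 7 without vehicle replicate 3.

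The change of the GFP+/GFP− ratio asks directly whether the enrichment of a gene in reporter-positive cells depended on the odorant. Limma called 0 of 19572 genes (465 at an unadjusted p under 0.05, 236 higher and 229 lower) and 0 of 1080 receptors adjusted over the list alone (39 at an unadjusted p under 0.05, 31 higher and 8 lower), so no receptor met the rule for a candidate. The receptors with the smallest p were Olfr393 at 1.84 (SE 0.43), Olfr1126 at 1.54 (SE 0.38) and Olfr117 at 1.51 (SE 0.37), followed among others by Olfr796 at 2.02 (SE 0.53), Olfr130 at 1.28, Olfr123 at 1.11, Olfr139 at 1.10 and Olfr132 at 1.00. For Olfr796, Olfr1126 and Olfr123 the ratio rose with a fall in GFP− cells (−1.96, −1.40 and −1.58). Their differences in GFP+ cells were 0.06 (SE 0.36), 0.14 (SE 0.24) and −0.47 (SE 0.26). Olfr117 was lower in GFP+ than in GFP− cells by −2.39 after vehicle and −0.88 after 2-octanone. Olfr139 was at background in GFP+ cells after vehicle. Olfr1098 stood at −1.69, and the exchange factor gene Plekhg4, whose signal was near background, at −1.05 (SE 0.23). In a single simulated data set the ratio test recovered 0 of 10 changed receptors over the list alone at a change of 1 and 4 of 10 at 2, so smaller changes would mostly be missed. Without vehicle replicate 4, 3 receptors were called over the list alone, Olfr796 (2.48), Olfr117 (1.87) and Olfr130 (1.68), each with an adjusted p of 0.0212. Without both replicate 4 pools 1 was called, Olfr796 (2.58, adjusted p = 0.0175). In GFP− cells Olfr796 stood at −2.41 without vehicle replicate 4 and at −2.29 without both replicate 4 pools.

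In the ratio, camera called 4 lists, all upwards. These were neutrophil genes (median 1.67, adjusted p = 0.000483; 0.874 with an estimated correlation), globose basal genes with Kit at 0.84 (median 0.34, 0.000483; 0.255 with an estimated correlation), immature OSN genes (median 0.28, 0.00752; 0.874 with an estimated correlation) and immediate early genes with Nr4a2 at 1.46 (median 0.30, 0.00875; 0.874 with an estimated correlation). With the pool as a block 5 were called, proliferation genes in addition (adjusted p = 0.0264). The immediate early call was lost without octanone replicate 1 (0.190) or 3 (0.250), the immature OSN call without octanone replicate 4 (0.150), and without vehicle replicate 4 the neutrophil list alone was called, with 0.203 for the immediate early and immature OSN lists and 0.176 for the globose basal list. Without both replicate 4 pools 1 list was called, the immediate early genes (adjusted p = 0.000329), with 0.0707 for neutrophil genes.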

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

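All tests weighed in this part, and the splits of the arrays, were chosen or scored after the results they address had been seen. Among 74 named genes in the 4 groups, 25 of 296 groups of 4 arrays held a value far from the other 3 (Dixon's test), where chance gives about 1 in 20, and 21 of the 25 lay on arrays of the replicate 4 pools. S100a5 stood apart in all 4 groups, at 13.92 and 13.22 in GFP+ cells and 13.55 and 13.11 in GFP− cells after 2-octanone and vehicle. In vehicle replicate 4 GFP− cells this held for Omp (17.76), Ano2 (16.19), H2-Ab1 (13.62), Pde2a (11.98), Olfr796 (9.51), Taar7a (9.01), Olfr398 (8.78), Kcnn3 (5.72), Vmn2r33 (5.51) and Olfr372 (4.51). In vehicle replicate 4 GFP+ cells it held for Olfr536 (13.25), Fos (10.88), Lcn2 (10.24) and Olfr372 (7.90). In octanone replicate 4 it held for Tekt1 (12.05) and Olfr372 (7.56) in GFP+ cells and for Taar7a (8.61) in GFP− cells. The other 4 were Olfr1098 (7.59, octanone replicate 1, GFP+), Olfr132 (12.50, octanone replicate 1, GFP−), Camk2n1 (8.51, vehicle replicate 1, GFP−) and Cxcl9 (4.74, octanone replicate 3, GFP−). No explanation for the replicate 4 pools was tested.

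The difference between exposures was not alike in GFP+ and GFP− cells in the list test for neutrophil (median 1.67), globose basal (0.34), immediate early (0.30) and immature OSN genes (0.28). With an estimated correlation none of these was called (camera adjusted p = 0.874, 0.255, 0.874 and 0.874), and fry called 0 lists. These lists were all lower in GFP+ cells in the sort. GFP− material in the GFP+ fractions of octanone pools 3 and 4, weighed below for neutrophil genes, would raise each of their ratios. Its share in the other lists was not tested. The globose basal and immature OSN medians were also negative in GFP− cells (−0.18 and −0.27). Among the 2634 probe sets that name no gene, 596 were called between GFP+ and GFP− cells, 324 higher and 272 lower, and 0 in either comparison of exposures by limma.

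The first pattern is the higher neutrophil signal in GFP+ cells after 2-octanone, seen in octanone pools 3 and 4. GFP− material in these fractions would bring the other transcripts of GFP− cells in the same proportion, and receptors found mainly in GFP− cells showed nearly the neutrophil share: 2.44% against 2.53% of the pool's GFP− signal in pool 3 (ratio 0.966) and 6.24% against 6.74% in pool 4 (ratio 0.925), while pools 1 and 2 had −0.17% and −0.08% for neutrophil genes. This is consistent with a small carry-over of GFP− cells or their RNA past the sort gate, though the macrophage genes showed 6.89% in pool 4 but −0.33% in pool 3, within the −3.49 to 1.76% of the vehicle pools. Of 8 receptors with positive differences in GFP+ cells, Olfr393, Olfr1213, Olfr459, Olfr1384, Olfr390 and Olfr1042 had their highest shares in pool 4 (6.71 to 15.3%, with 1.20 to 4.54% in pool 3 and −0.02 to 2.82% in pools 1 and 2), so that carry-over stays open for part of their differences, while Olfr77 would need 1.56, 3.88, 8.51 and 7.60% in the 4 pools and Olfr117 14.1 to 48.5%, above the neutrophil share in each. More neutrophils in the mucosa, the biological explanation, would raise both fractions alike, which is argued against as the whole cause: the GFP+ minus GFP− mean of the neutrophil genes exceeded that of the vehicle pools by 2.67 in pool 3 and 4.06 in pool 4 (limit for a single pool 0.685), with −0.346 and 1.05 in their GFP− cells (limit 1.65), so that a part of the rise in pool 4 stays open.

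The second pattern is the lower signal of Olfr123, Olfr796 and Olfr1126 in GFP− cells after 2-octanone. Fewer transcripts in both fractions would lower them in GFP+ cells as well, which is argued against for Olfr796 (0.0601, SE 0.361, against −1.96) and Olfr1126 (0.138, SE 0.243, against −1.40) but stays open for Olfr123 (−0.472, SE 0.257, against −1.58). Fewer neurons among the GFP− cells would lower all receptors, whose median difference was 0.0156. That neurons with these receptors moved into the GFP+ fraction stays open as a hypothesis: 2 of the 3 had a higher mean in GFP+ cells, and the size of the rise it needs could not be set because the sizes of the fractions are not given in the sources used here. Among 35 splits of the 8 pools the GFP− cells gave as many genes in 2 and as many receptors in 5, so chance is not excluded.

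Of the splits of the arrays, the real one included, 1 of 100 gave as many genes between GFP+ and GFP− cells over both exposures (6000, highest other 1), 1 of 35 after vehicle (3633, highest other 1) and 1 of 35 after 2-octanone (2955, highest other 0); these splits ignore that the fractions are paired by pool. With fractions exchanged only within pools, 1 of 100 gave as many genes over both exposures (6000, highest other 3158, from the exchange of a single pool). That share is under 0.05 and is the smallest that 100 splits can give. The fractions were sorted on GFP, so a difference between them was built into the design. Within one exposure only 8 splits part all 4 pools (highest other 0 after vehicle and 0 after 2-octanone), too few for a share under 0.05. For the lists in the sort 13 of 100 gave as many (14, highest other 16), and 19 of 100 within pools (highest other 18). In GFP+ cells after 2-octanone 28 of 35 gave as many lists (2, highest other 12). Among the 8 splits that part all 4 pairs of replicate numbers, as the real one does, 4 gave as many lists (highest other 3), and the highest other was 0 genes and 2 receptors. In GFP− cells 2 of 35 gave as many genes (1, highest other 1), 5 as many receptors (3, highest other 137) and 30 as many lists (3, highest other 18). Among the 8 splits that part all 4 pairs, 1 gave as many genes (highest other 0), 1 as many receptors (highest other 0) and 6 as many lists (highest other 11). These 8 are too few to decide. For the ratio 19 of 35 gave as many lists (4, highest other 12). Chance is not excluded for these counts of lists, or for the genes and receptors in GFP− cells. Where the real count was 0, as for genes and receptors in GFP+ cells and the ratio, all 35 of 35 splits gave as many by construction, so they decide nothing: the highest other was 2 genes and 19 receptors in GFP+ cells and 0 genes and 1 receptor for the ratio. The split with 137 receptors in GFP− cells differs from the exposures by an exchange of octanone replicate 1 and vehicle replicate 4. A split of replicates 1 and 3 from 2 and 4, with both exposures equally on each side, gave 66. Counts so far above the real one point to a structure of the samples, and what it reflects was not tested.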

How the results depend on the processing

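Leaving out both replicate 4 pools, array weights, the neutrophil covariate and single pools left out of the list tests were chosen after seeing the data. For single genes named by the rule, 221 results over the alternatives kept direction and side of the threshold 3971 times, passed it in 26 cases, no longer passed it in 39 and reversed in 13, none called either way. With single pools left out S100a5 ran from −0.465 to 1.09 in GFP+ cells and −0.388 to 0.776 in GFP− cells. In the ratio it ran from −0.0777 to 0.313. Omp ran from −0.0490 to 0.146 in GFP− cells and −0.128 to 0.0713 in the ratio. Each of these reversed without vehicle replicate 4, a setting that keeps octanone replicate 4, where S100a5 is low too. Omp also reversed in GFP− cells (−0.0557) and the ratio (0.121) after quantile normalisation, in both without both replicate 4 pools (−0.0147 and 0.0513) and in the ratio with array weights (0.0103). Sox11 reversed in GFP− cells without both replicate 4 pools (0.21) and with array weights (0.106), and Kdr in the sort after median centring (0.0848). For lists 23 results kept both 245 times and no longer passed in 54. Median centring called 15141 genes in the sort, 11289 after vehicle and 9535 after 2-octanone, while leaving out dim probe sets, which tests fewer genes, called 3664, 2221 and 1811. Of the 6000 genes 5315 were shared with median centring, 3391 with dim probe sets left out, 5259 with quantile normalisation, 5779 with the pool as a block and 4727 without both replicate 4 pools. With single pools left out the count after 2-octanone was 1963 to 3496. In GFP− cells the number of genes was 0 with only the arrays compared and 0 with the replicate number as a block. It was 0 with the pool as a random block, 2 with array weights and 0 to 2 with single pools left out. With the number block Olfr123 was not called over all genes (limma adjusted p = 0.171). Over the list alone that block called Olfr123 (limma adjusted p = 0.00944), Olfr796 and Olfr1126 (0.0113 each) and Olfr398 (0.0122), all lower. The number of receptors over the list alone was 1 with only the arrays compared and 1 to 4 with single pools left out. Receptors in GFP+ cells numbered 1 with the replicate number as a block, 1 with array weights and 0 to 1 with single pools left out. For the ratio receptors numbered 1 without both replicate 4 pools, 1 with array weights and 0 to 3 with single pools left out. An estimated correlation called 3 lists in the sort and 0 in each other comparison, and fry called 19 in the sort, 0 in GFP+ cells, 0 in GFP− cells and 0 for the ratio. Lists numbered 5 in GFP+ cells with the number block, 0 in GFP− cells and 2 for the ratio with array weights, and 1 for the ratio without both replicate 4 pools. With single pools left out they numbered 2 to 7 in GFP+ cells, 2 to 7 in GFP− cells and 1 to 6 for the ratio. The blocks changed no other count by over 1.5 times; single-gene calls that changed are among those counted above. Median centring raises every difference in the sort by the same amount, and leaving out dim probe sets tests fewer genes. For the other changes the cause was not tested. Signals near the background of 5.40 to 5.61 limit what can be seen of dim genes. Where a single side of a comparison lies there, the difference is a lower bound in size. Where both sides do, as for Vmn2r40 and Vmn2r33, the difference sets no bound.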

Other observations

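The mean of both fractions, the class and the neighbour tests in this part were chosen after the other results were seen. Taking the mean of both fractions of each pool, limma called 0 of 19572 genes between 2-octanone and vehicle (425 at an unadjusted p under 0.05). Olfr123 differed by −1.03 (SE 0.105, adjusted p = 0.0504), and Pcdh10, lower in GFP− than in GFP+ cells but with a like difference between exposures in both, by 2.04 (SE 0.45). Camk2n1 differed by 0.72.

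A hypothesis was that class I receptors, a group known for ligands such as carboxylic acids, respond more to 2-octanone than class II receptors. The median change of the ratio differed by −0.0481 between 121 class I and 940 class II receptors (permutation p = 0.309, adjusted 0.412, 10000 permutations, 19 receptors unplaced), which leaves it undecided. In GFP− cells the medians differed by 0.0942 (permutation p = 0.00730, adjusted 0.0292) and in GFP+ cells by 0.0324 (adjusted 0.412), with receptors not independent of each other. A further hypothesis was that the 12 receptors with the strongest rise of the ratio lie next to each other in the genome, at most 5 receptor genes apart. They held 1 such pair, and 29 of 35 splits of the pools gave as many (highest other 4), so chance is not excluded. In the order of receptor genes Olfr117, Olfr123, Olfr130 and Olfr132 held places 293, 299, 307 and 309. Olfr393 and Olfr139 held 153 and 159, and the others lay further apart. The count thus depends on the limit of 5, and no other limit was tested.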
